A study of Mus musculus with 3 samples.

How the data were processed

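Total RNA of the mouse embryonic stem (ES) cell line E14.1 was measured at 3 time points of a differentiation towards hepatic cells, with 1 Cy3-labelled Agilent whole-genome expression array per time point. Per the labels' protocols, ES cells were kept in serum-free N2/B27 medium with LIF and BMP4 (day 0), then moved to collagen IV with activin A in place of LIF and BMP4 (day 5, definitive endoderm), and then kept for 2 more days with BMP4 and basic FGF added to activin A (day 7, early hepatic cells). Groups were taken from the cell type given in the labels. There were no replicates, so no test, p-value or standard error was possible, and every difference between days is a difference between 2 arrays.

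Per the file headers, the authors scanned the arrays and extracted them with Agilent Feature Extraction 10.5.1.1, with spatial detrending, and the probe positions are those of the mouse genome build mm9 (NCBI37). The deposited scanner files hold 1 fluorescence intensity per spot on a linear scale, of which the processed signal (background-corrected by that software) was used here. The mean signal and the median local background of each spot, also intensity values in the deposited files, were used for an alternative background correction. The deposited value table holds log2 values of 41252 probe rows. Set against the log2 processed signals of the same arrays, each of its columns correlated across probes at r = 0.9998 or above, all 3 columns had a median of 7.1678, and the sorted columns differed by up to 0.0005 (log2) at any rank, so that the authors' table holds log2 intensity made equal in distribution between arrays; it is uncentred per gene, and the step that equalised the arrays is not given in the sources used here.

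Each array held 43379 gene spots of 41174 gene probes. The processed signal was converted to log2, and each array's 75th percentile over the gene spots was subtracted. A normalised log2 signal of 0 is therefore the array's 75th percentile. Spots marked by the extraction software as non-uniform or as population outliers were left out (149 on day 0, 104 on day 5 and 131 on day 7), as were control spots, and spots of 1 probe were averaged. No gene spot was saturated. A probe counted as well above background on an array when more than 50% of its spots carried that mark. Probes were named through RefSeq accessions in a table of the assembly GRCm38.p6 (24836 probes) or through their symbol in that table (6051 probes). The other 10287 probes kept the name in the files, so that the names counted as genes here include transcripts known only by a clone or accession. A gene was represented by the probe that was well above background on the most arrays and, among equals, by the brightest. Of 28577 names with a value on all arrays, the 21653 whose probe was well above background on at least 1 array entered the comparisons.

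A gene was called higher or lower when its probe was well above background on the brighter array and the difference was at least 1 on the log2 scale (2-fold). A dim probe that was not well above background was set to the higher of its own value and the lowest value among probes well above background on that array, and the difference is then given as "at least N-fold". A gene dim on both arrays was given a difference of 0, as was a bound that would otherwise change sign. A list median of 0.00 can therefore come from dim genes and is not a measured absence of change. The named genes were fixed by a rule before the data were examined. The rule took, for each comparison, the 8 largest and the 8 smallest differences measured on both arrays (leaving out clone, accession, RIKEN, LOC and Gm names), up to 4 members at least 2-fold higher and up to 4 at least 2-fold lower of each gene list described, and a fixed set of 29 marker genes whatever their values. The values of a few genes that the rule takes are not reported. The 33 gene lists, with markers of other cell types among them, were also fixed before the data were examined. A list's median difference was set beside the medians of 10000 random lists of the same size matched on mean signal in 20 bins, as a description of these arrays only, and a list is said to stand apart when its median lay outside the central 95% of the random lists.

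The only replicate measure was technical. Per array, between 192 and 196 of the 245 probes printed as 10 spots were bright enough to give a spot SD, and the median SD was 0.080 (day 0), 0.076 (day 5) and 0.077 (day 7) on the log2 scale. Fewer than 0.1% of spot pairs of 1 probe differed 2-fold. In 100 simulations with this spot noise alone and no difference between days, at most 7 genes passed the 2-fold limit in any comparison. This spread leaves out culture, RNA and labelling, so it cannot say how a repeat of the experiment would differ. All 3 arrays lay on 1 slide. The number of arrays limits the precision.

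The calling step was tested on simulated data in which 50 genes at each of several sizes of change, of the 21653 genes, were changed by known amounts. For day 5 against day 0, it recovered 88.0% of genes changed by 1.5 on the log2 scale and 90.0% of those changed by 2.0, with 0 unchanged genes called; in each of the other comparisons 2 unchanged genes were called. The genes it missed had been lowered towards, or lay at, the background. The list step put 20 of 20 simulated lists shifted by 2 outside the central 95% of random lists, and 0 of 20 lists with no shift.

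Alternatives fixed before the data were examined were scaling to the median, scaling to the 75th percentile of probes well above background on all arrays, quantile normalisation, normexp background correction with an offset of 50, the authors' value table, no filter on dim probes, only probes well above background on all arrays, removal of saturated spots, the median over a gene's probes, and thresholds of 1.5-fold and 4-fold. A second normexp correction, fitted without spots of outlying local background, was added after the first had been seen. It kept the offset of 50. The lowest processed signals well above background were 14.09 (day 0), 18.86 (day 5) and 15.62 (day 7). The offset by itself therefore makes folds with a dim side smaller, and smaller differences of dim genes under the refit do not show an effect of the background fit alone. The 5 other scalings named below are the median and 75th percentile scalings, quantile normalisation, the authors' value table and the second normexp correction. The last of these is a background correction rather than a scaling between arrays. Computations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and R 4.3.3 with limma 3.58.1 for normexp and quantile normalisation.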

Results

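Gene expression was measured on 3 one-colour arrays, 1 each for undifferentiated E14.1 mouse ES cells (day 0), ES cell-derived definitive endoderm (day 5) and ES cell-derived early hepatic cells (day 7). Definitive endoderm is the embryonic germ layer from which liver, pancreas and gut arise. Of 43379 gene spots per array, 71.7% were well above background on day 0, 70.9% on day 5 and 71.6% on day 7. The 75th percentile of the processed signal was 1564, 2051 and 2053 intensity units. With 1 array per day, none of the differences below has a replicate check. On the scale used here, the median difference over all genes well above background on both arrays was -0.13 (log2) for day 5 against day 0, -0.20 for day 7 against day 0 and -0.09 for day 7 against day 5, and the differences below are to be read against these shifts. The random lists set beside each gene list carry the same shift. Many folds depend on the background correction and the probe: of named differences of at least 2-fold, 194 of 498 were over 1.5 times smaller with the refitted normexp correction, and 67 of 526 with the median over a gene's probes, so that the order of the largest differences holds for the main setting only.

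The series was set up around Foxa2, a forkhead transcription factor of the endoderm and liver, which the labels describe as not expressed in the day 0 cells. Its probe (chromosome 2, 147868698 to 147868757, mm9) is printed as 10 spots per array. Its normalised log2 signal was -4.22 ± 0.105 on day 0, 4.29 ± 0.070 on day 5 and 3.98 ± 0.091 on day 7 (mean ± SD of 10 spots of 1 array, a technical spread only). Foxa2 was thus 364-fold higher on the day 5 array and 294-fold higher on the day 7 array than on the day 0 array. On day 0 the probe was dim, at 0.0536 of the array's 75th percentile, but still marked as well above background. Day 7 lay 1.24-fold below day 5. The related factor Foxa1 was at least 148-fold higher on day 5 and at least 87.4-fold higher on day 7 than on day 0, where it was not well above background. Foxa3 was 9.80-fold and 8.80-fold higher than on day 0.

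The comparison of day 5 with day 0 asks what distinguished definitive endoderm from the ES cells it was made from. Genes of the primitive streak and of definitive endoderm were far higher on day 5, and genes of the ES cell state were far lower. The largest differences measured on both arrays were those of Asb4 (1327-fold), Lhx1 (1066-fold), Prss12 (819-fold), Sema6d (745-fold), Cyp26a1 (723-fold), Gsc (537-fold), Myocd (470-fold) and Foxa2. Lhx1 and Gsc are transcription factors of the anterior primitive streak, and Cyp26a1 breaks down retinoic acid. The genes furthest below day 0 were Khdc3 (265-fold lower), Scgb3a1 (141-fold), Gtsf1 (117-fold), Vax2 (109-fold), Nupr1 (108-fold), Rpl39l (96.5-fold, but -2.74 on the log2 scale with the refitted normexp correction), Morc1 (91.8-fold) and Bcl3 (85.3-fold). In all, 3564 genes were at least 2-fold higher and 3484 at least 2-fold lower among the 21653 compared. For 638 and 567 of these, only a bound was available because the dimmer array was not well above background.

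**Figure D1:**
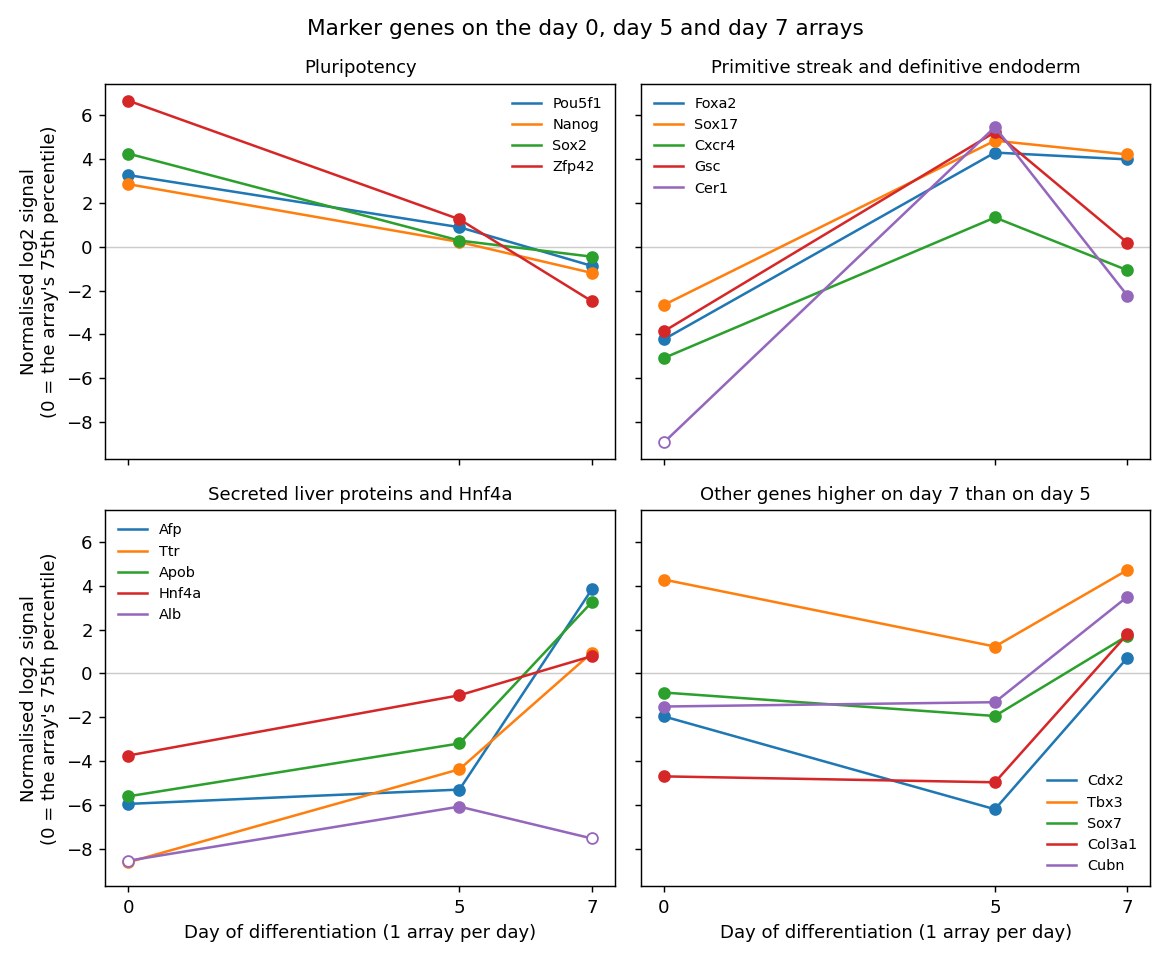
Normalised log2 signal (0 is the array's 75th percentile) of marker genes by day of differentiation, with 1 array per day; open circles are probes not well above background, and levels of different probes cannot be compared with each other. Foxa2 reads -4.22, 4.29 and 3.98 on days 0, 5 and 7, Pou5f1, Nanog, Sox2 and Zfp42 are lower on each later day, and Afp is 557-fold higher on day 7 than on day 5.

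Of 17 measured genes of naive pluripotency, 16 were at least 2-fold lower on day 5 and 0 were higher (median log2 difference -4.90, against -0.57 to 0.43 for the central 95% of random lists). They included Esrrb (57.1-fold lower), Fbxo15 (54.2-fold), Klf4 (45.7-fold) and Nr5a2 (42.5-fold), and Zfp42 (Rex1), a classical ES cell marker, was 42.4-fold lower. Among 12 general pluripotency genes, 9 were lower and 0 higher (median -2.50, random -0.65 to 0.60). In this group the difference in Pou5f1 (Oct4) was smaller, at 5.19-fold, than in Sox2 (15.6-fold), and Nanog was 6.21-fold lower. Targets of LIF and STAT3, the pathway that the day 0 medium activated through LIF, were lower for 10 of 12 genes (median -3.06, random -0.66 to 0.52), with Bcl3 at 85.3-fold and Socs3, the feedback inhibitor of that pathway, at 49.2-fold. Germ cell and early cleavage-stage genes were lower for 6 of 11 and higher for 2 (median -1.98, random -0.71 to 0.71). Mael, a factor of the germ line, was 41.0-fold lower, and Tcstv1 was 33.7-fold higher.

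Genes of the primitive streak and mesendoderm, the transient stage before endoderm, were higher on day 5 for 13 of 15 members, with 0 lower (median 3.59, random -0.60 to 0.58). Besides Lhx1 and Gsc, Fgf8 was 110-fold and Eomes 108-fold higher. T (Brachyury) was only 3.93-fold higher, and Mixl1 was at least 30.6-fold higher. Of 20 definitive endoderm genes, 17 were higher and 1, Fgf17 (21.9-fold), was lower (median 5.27, random -0.51 to 0.49). Sox17, a transcription factor required for endoderm, was 179-fold higher. The Wnt antagonist Dkk1 was 186-fold and Gata6 111-fold higher, although 1 of 2 other Gata6 probes differed by less than 2-fold. Cer1, a secreted inhibitor of Nodal, was at least 4845-fold higher, Cxcr4, a surface marker used to sort endoderm, 84.6-fold, Hhex 19.4-fold and Gata4 9.39-fold. Targets of Nodal and activin, the signal supplied in the medium, were higher for 9 of 12 genes and lower for 2 (median 3.45, random -0.66 to 0.58, and 1.57 over probes well above background on all arrays), among them Lefty1 (129-fold), while Tdgf1, the Nodal co-receptor, was 2.18-fold lower, and under 2-fold in the authors' value table. This target list shares Lefty2, Nodal, Gsc, Mixl1, Eomes and Foxh1 with the primitive streak list. It also shares Cer1 with the definitive endoderm list and Tdgf1 with the general pluripotency list, so it is not separate evidence from theirs. Wnt targets were higher for 7 of 12 (median 1.42, random -0.64 to 0.72), with Sp5 20.6-fold higher and Notum 6.64-fold lower. The Wnt list shares T and Sp5 with the primitive streak list and Dkk1 with the definitive endoderm list. It also shares Lef1 with the epiblast list, and Lgr5 and Cdx1 with the intestine and stomach list. Its medians are therefore not fully separate evidence in any of the 3 comparisons. Genes of the postimplantation epiblast were higher for 6 of 10 (median 1.37, random -0.68 to 0.68), led by Fgf5 (132-fold), Zic2 (8.69-fold), Otx2 (4.30-fold) and Dnmt3b (4.02-fold).

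Genes of the liver were mixed on day 5. Among 15 hepatic transcription factors, 5 were higher and 6 lower than on day 0 (median -0.26, inside the random range). Hnf4a was 6.70-fold and Prox1 5.45-fold higher; each had 1 other probe within 2-fold, and with the median over its probes Hnf4a was higher by only 0.60 on the log2 scale. Nr5a2 (42.5-fold) and Tbx3 (8.29-fold), both also expressed in ES cells, were lower. Of 22 secreted liver proteins, 9 were higher and 5 lower, and the median of 0.27 lay inside the random range, above it in 3 alternatives, and below 0 in 2, at -0.18 with the refitted normexp correction and -0.16 over probes well above background on all arrays. Ambp was 101-fold and the retinol carrier Rbp4 20.2-fold higher, Apoa1 at least 46.9-fold and Ttr at least 5.37-fold higher. Ahsg (37.8-fold), Apom (10.1-fold), Apoc1 (6.44-fold) and Trf (5.81-fold) were lower. Afp, the main serum protein of fetal liver and yolk sac, differed by 1.57-fold. Alb was just above background on day 5 only, at 0.0149 of that array's 75th percentile. The list of 12 known Foxa2 targets had 4 members higher and 2 lower (median 0.33, inside the random range, and -0.52 over probes well above background on all arrays), and enzymes of mature hepatocytes had 2 of 13 higher and 3 lower (median -0.15, inside the random range).

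Markers of other cell types also differed on day 5. Extraembryonic endoderm genes were higher for 12 of 20 and lower for 3 (median 1.60, random -0.54 to 0.38). Pdgfra was 71.0-fold and the basement membrane collagen Col4a2 8.96-fold higher, whereas Lama1 was 12.6-fold and Rhox5 8.44-fold lower. Sox7, expressed in extraembryonic but little in definitive endoderm, was 2.10-fold lower, a difference under 2-fold with the median over its probes or the refitted normexp correction. Cardiac and lateral mesoderm genes were higher for 9 of 16 and lower for 3 (median 1.52, random -0.56 to 0.59, and 0.63 with the refitted normexp correction). The higher ones included Tbx20 (12.3-fold) and Hand2 (7.52-fold, and under 2-fold with that correction), whereas Myl2 was lower (-3.80 on the log2 scale). Fibroblast and mesenchyme genes were higher for 7 of 19 and lower for 3 (median 0.59, random -0.56 to 0.48). Cdh2 (24.4-fold), Col1a2 (18.1-fold) and Zeb2 (16.2-fold) were in front, and Thy1 was lower (-2.55 on the log2 scale). This list no longer stood apart with the refitted normexp correction, and Cdh2 differed by only 0.27 (log2) with the median over its probes. Epithelial junction and keratin genes were higher for 9 of 18 and lower for 2 (median 1.05, random -0.55 to 0.32), led by the simple-epithelium keratins Krt18 (7.96-fold), Krt7 (2.718 on the log2 scale) and Krt8 (6.56-fold). Proliferation genes were lower for 12 of 22 and higher for 0 (median -1.09, random -0.54 to 0.05), as in Ccne1 (5.06-fold) and Mcm5 (3.17-fold).

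The comparison of day 7 with day 0 covers the whole route from ES cells to early hepatic cells. Afp and Apob, proteins of fetal liver and yolk sac, were among the largest differences with Foxa2, and 6 of 12 general pluripotency genes were lower still than on day 5. The largest measured differences were Prss12 (1801-fold), Afp (875-fold), Tfec (555-fold), Apob (460-fold), Asb4 (350-fold), Myocd (336-fold), Cyp26a1 (328-fold) and Foxa2. Esrrb was 1370-fold lower, Khdc3 1034-fold, Ooep 659-fold, Dpys 612-fold, Tekt1 591-fold, Zfp42 562-fold, Rbmxl2 463-fold and Liph 445-fold. In all, 3509 genes were higher and 4137 lower, of which 601 and 738 are bounds. Of the 3564 genes higher on day 5, 2447 were also higher on day 7, and of the 3484 lower, 2900 were also lower. Independent lists of these sizes would share 578 and 666, and 100 simulations with spot noise alone and no difference between days shared 0, a value that leaves out any spread between arrays or cultures. Both comparisons use the same day 0 array, so part of the excess may come from that array.

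Naive pluripotency genes were lower for 15 of 17 and higher for 0 (median -5.76, random -0.67 to 0.44). Tbx3, one of the exceptions, stood 1.35-fold above day 0. General pluripotency genes were lower for 9 of 12 (median -4.13, random -0.73 to 0.63), with Gdf3 at 300-fold, Sox2 at 25.9-fold, Pou5f1 at 17.6-fold and Nanog at 16.5-fold. Primitive streak genes were higher than in ES cells for 12 of 15 members (median 3.65, random -0.68 to 0.61), including Lhx1 (110-fold), Eomes (51.2-fold) and Mesp1 (34.0-fold). Definitive endoderm genes were higher for 15 of 20 and lower for 2 (median 3.92, random -0.63 to 0.47). Nepn (261-fold), Tmprss2 (175-fold) and Sox17 (116-fold) followed Foxa2, and Trh was 68.2-fold lower.

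Secreted liver proteins were higher than in ES cells for 12 of 22 and lower for 6 (median 2.22, random -0.66 to 0.31, and at least 1.19 under the alternatives). Next to Afp and Apob stood Ttr, the thyroid hormone carrier (at least 213-fold), the fibrinogen chain Fgb (96.3-fold), Apoa1 (at least 58.4-fold) and Apoc2 (29.7-fold). Alb was not well above background on day 0 or day 7, so that no fold can be given. Ahsg (25.3-fold), Apoc1 (12.2-fold), Trf (5.70-fold) and Fgg (2.34-fold) were lower. Hepatic transcription factors again went both ways, with 5 of 15 higher and 4 lower (median -0.03, inside the random range, and above 0 under 3 of 5 other scalings). Hnf4a was 23.1-fold (1.62 on the log2 scale with the median over its probes) and Prox1 8.11-fold higher, the last with 2 other probes within 2-fold and a difference of only 0.24 (log2) with the median over its probes. With that median over probes the list lay below the random range. Nr5a2 was 202-fold lower. Known Foxa2 targets were higher for 5 of 12 and lower for 2 (median 0.00, inside the random range). This median was -0.42 over probes well above background on all arrays and 1.01, above the range, with no filter on dim probes. Of 13 mature hepatocyte enzymes 3 were higher, among them Tdo2 (17.6-fold) and Arg1 (5.24-fold, and under 2-fold with the refitted normexp correction), and 3 were lower, among them Cps1, the first enzyme of the urea cycle (at least 9.43-fold; median -0.19, inside the random range).

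Extraembryonic endoderm genes were higher on day 7 than on day 0 for 16 of 20 (median 3.10, random -0.63 to 0.40), with Tfec at 555-fold, the endocytic adaptor Dab2 at 112-fold and Ihh at 103-fold. Fibroblast and mesenchyme genes were higher for 15 of 19 (median 3.73, random -0.65 to 0.47), including Postn (184-fold), Col3a1 (89.2-fold, with 1 other probe within 2-fold) and Twist2 (37.4-fold). Cardiac and lateral mesoderm genes were higher for 12 of 16 (median 2.37, random -0.71 to 0.54), among them Tbx20 (29.7-fold) and the sarcomere gene Tnnt2 (13.7-fold), and 1, Myl2, was lower (-6.01 on the log2 scale). BMP targets were higher for 8 of 14 and lower for 2 (median 1.91, random -0.70 to 0.54), with Msx2 22.5-fold higher and Id4 lower (-4.09 on the log2 scale). Wnt targets were higher for 9 of 12 (median 2.76, random -0.73 to 0.71). LIF and STAT3 targets were lower for 8 of 12 (median -2.20, random -0.74 to 0.54), and proliferation genes for 14 of 22 (median -1.03, random -0.65 to 0.03, and -0.68 with quantile normalisation). Epithelial genes were higher for 7 of 18 and lower for 4 (median 0.86, random -0.66 to 0.30, and 0.56 with the refitted normexp correction), Krt19 by 9.49-fold.

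The comparison of day 7 with day 5 covers the last step, in which BMP4 and basic FGF were added for 2 more days of culture. Effects of the added factors and of the longer culture cannot be told apart. Afp, Apob, the caudal gut factor Cdx2 and the collagens Col1a1 and Col3a1 were higher on day 7, and the secreted Nodal inhibitors Cer1, Lefty1 and Lefty2 were lower. The largest measured differences were Afp (557-fold), Lgals2 (301-fold), Cdx2 (119-fold), Col3a1 (108-fold, with 1 other probe within 2-fold), Gc, the vitamin D carrier of serum (105.2-fold), Apob (86.8-fold), Postn (86.6-fold) and Fmo1 (83.2-fold). On the other side, Cer1 was 205-fold, Lefty1 110-fold, Alx1 81.6-fold, Trh 51.6-fold, Ntrk2 36.8-fold, Lefty2 34.9-fold, Gsc 32.8-fold and Cdhr1 30.6-fold lower. Cdx2 was already well above background on day 0, and differed from it by -4.23 (log2) on day 5 and 2.67 on day 7. Part of its rise after day 5 thus made up for a fall before it. Fewer genes differed than in either comparison with ES cells, 1292 higher and 1815 lower, of which 281 and 384 are bounds.

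Secreted liver proteins were higher on day 7 than on day 5 for 10 of 22 and lower for 3 (median 0.45, random -0.34 to 0.09, and 1.53 over probes well above background on all arrays). Ttr was 39.7-fold and Apoc2 35.7-fold higher, while Ambp was 4.39-fold lower, and Alb was not well above background on day 7. Hepatic transcription factors were higher for 3 of 15 and lower for 2 (median -0.09, inside the random range, and above 0 under 3 of 5 other scalings). Tbx3, needed for outgrowth of the liver bud and also an ES cell factor, was 11.2-fold higher, and Hnf4a 3.44-fold (with 1 other probe within 2-fold), and Hlx was 5.00-fold lower. Known Foxa2 targets were higher for 5 of 12 and lower for 1 (median 0.14, inside the random range). Mature hepatocyte enzymes were higher for 3 of 13 and lower for 1 (median 0.20, random -0.47 to 0.18); this small excess was lost under 3 alternatives.

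Definitive endoderm genes were lower on day 7 than on day 5 for 9 of 20 and higher for 3 (median -0.82, random -0.30 to 0.13, and -0.47 over probes well above background on all arrays). Besides Cer1 and Trh, Frzb was 5.49-fold, Cxcr4 5.29-fold and Hhex 5.05-fold lower, whereas Sox17 (1.55-fold lower), Foxa1 (1.69-fold lower) and Gata4 (1.53-fold higher) stayed within 2-fold, like Foxa2. Targets of Nodal and activin were lower for 9 of 12 and higher for 0 (median -1.21, random -0.30 to 0.20), although activin A was still in the medium. That list shares genes with the primitive streak, definitive endoderm and general pluripotency lists, so its fall is not separate from theirs. Primitive streak genes were lower for 7 of 15 (median -0.86, random -0.31 to 0.17), with Lhx1 at 9.66-fold and Fgf8 at 7.62-fold, and Wnt3a was 12.8-fold higher. Epiblast genes were lower for 6 of 10 (median -1.26, random -0.36 to 0.20), among them Zic2 (5.59-fold) and Otx2 (4.81-fold). General pluripotency genes were lower for 6 of 12 and higher for 0 (median -1.17, random -0.31 to 0.18), with Pou5f1 3.39-fold and Nanog 2.65-fold lower. Naive pluripotency genes were lower for 7 of 17 and higher for 4 (median -0.77, random -0.28 to 0.14). The higher members were Tbx3, Klf4 (7.57-fold), Tfcp2l1 (3.27-fold) and Pecam1 (at least 2.74-fold, and under 2-fold with the refitted normexp correction), and the lower ones included Dppa5a (15.2-fold) and Zfp42 (13.3-fold). LIF and STAT3 targets, which share Klf4, Klf5 and Tfcp2l1 with that list, were higher for 7 of 12 and lower for 0 (median 1.45, random -0.29 to 0.17), Socs3 by 3.33-fold, although LIF was not added.

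**Figure D2:**
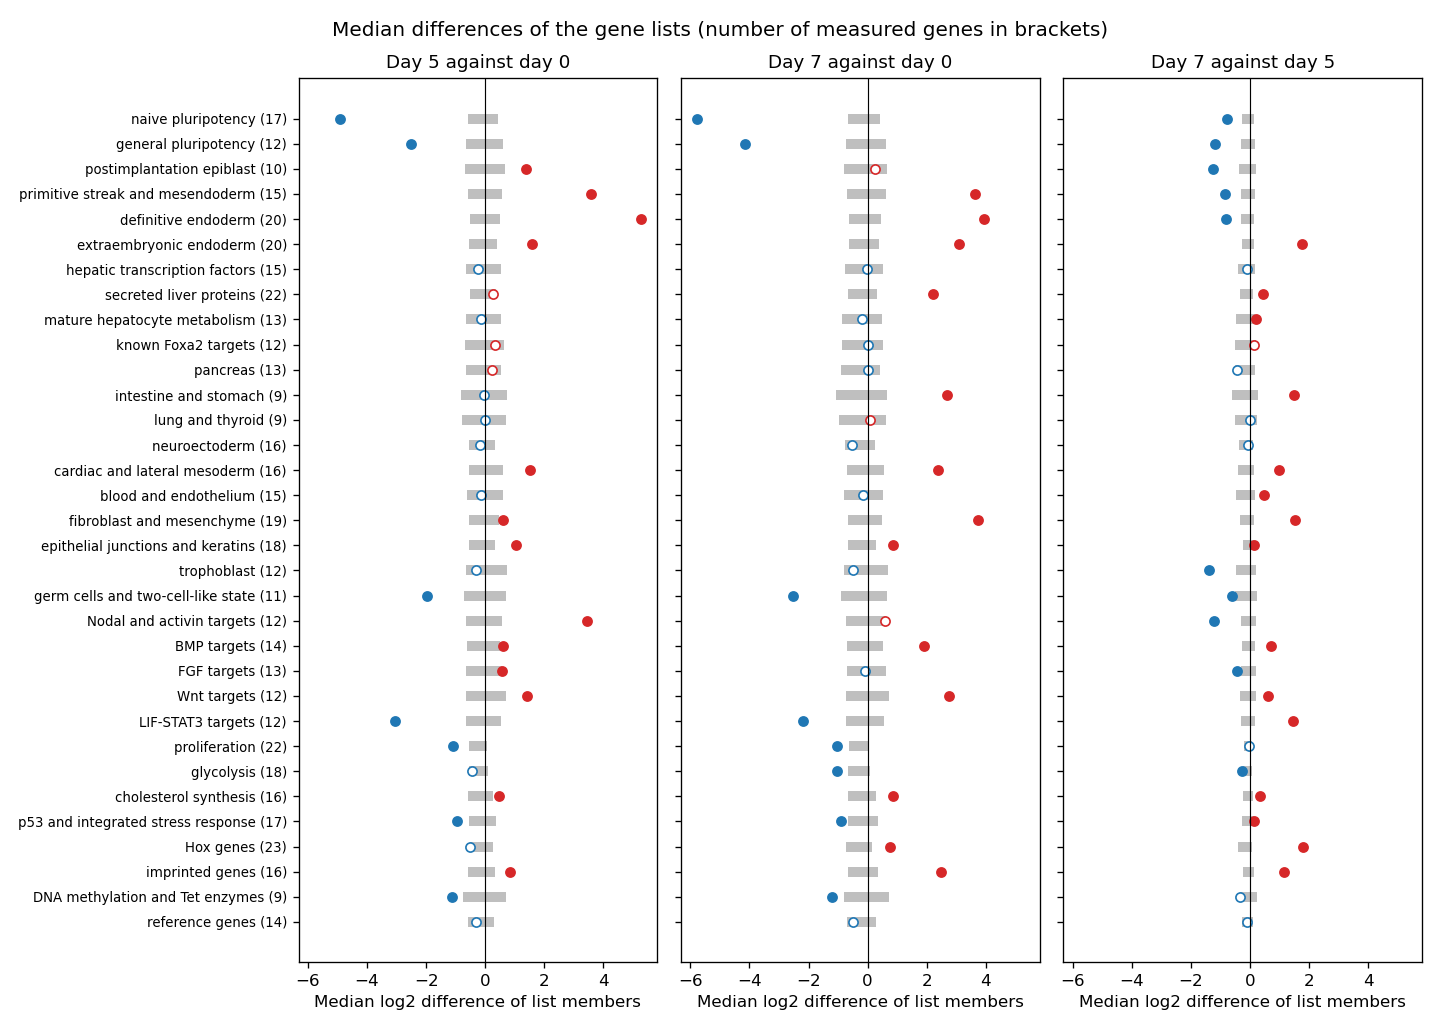
Median log2 difference of the measured members of each of the 33 gene lists (numbers of genes in brackets) in the 3 comparisons; grey bars span the central 95% of 10000 random lists matched on mean signal, and filled circles lie outside it. Definitive endoderm genes have medians of 5.27 and 3.92 against day 0 and -0.82 for day 7 against day 5, where extraembryonic endoderm, mesenchyme and Hox genes lie to the right.

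Extraembryonic endoderm genes were higher on day 7 than on day 5 for 13 of 20 and lower for 2 (median 1.76, random -0.26 to 0.13). Dab2 was 30.8-fold, Lama1 29.0-fold, the endocytic receptor Cubn 27.9-fold and Sox7 12.6-fold higher. Lama1 and Sox7 had been lower on day 5 than on day 0 (-3.655 and -1.069 on the log2 scale in the main setting). Part of their rise thus made up for that fall, and Sox7 lay 2.585 (log2) above day 0 on day 7. Intestine and stomach genes were higher for 5 of 9 (median 1.49, random -0.62 to 0.27, and 0.80 with no filter on dim probes), with Cdx2, Fabp2 (7.00-fold) and Vil1 (2.81-fold). Hox genes, which pattern the trunk from head to tail, were higher for 13 of 23 and lower for 0 (median 1.79, random -0.40 to 0.06, and 0.39 over probes well above background on all arrays). Hoxb2 was at least 103-fold higher, and Hoxa7 (3.63-fold) and Hoxb4 (3.47-fold) were higher at low signal, the latter by less than 2-fold with the refitted normexp correction. Fibroblast and mesenchyme genes were higher for 12 of 19 and lower for 0 (median 1.51, random -0.33 to 0.13), Col1a1 by 54.3-fold and Twist2 by 24.7-fold. Cardiac and lateral mesoderm genes were higher for 8 of 16 and lower for 3 (median 0.98, random -0.41 to 0.14); Tnnc1 was 15.8-fold and Hand1 15.6-fold higher, while Myl7 was 4.47-fold lower. Targets of BMP, which was added for this step, were higher for 5 of 14 and lower for 1 (median 0.72, random -0.29 to 0.17), led by Msx2 (25.4-fold). Against day 0 the same list had a median of 0.59 on day 5, when BMP4 had been left out, although this depended on the processing. On day 7 against day 0 it had 1.91, although both media held BMP4, so its rise cannot be assigned to BMP4 in the medium. Targets of FGF, also added, were higher for 0 of 13 and lower for 3 (median -0.43, random -0.30 to 0.19), Egr1 by 3.22-fold and Dusp6 by 2.66-fold, and this was lost with the median over a gene's probes. Wnt targets were higher for 3 of 12 (median 0.59, random -0.35 to 0.22). For proliferation genes, 0 of 22 differed by 2-fold (median -0.04, inside the random range, and above 0 under 2 of 5 other scalings and with the median over a gene's probes). Epithelial genes were higher for 1 of 18 and lower for 4 (median 0.14, random -0.24 to 0.12), with Krt7 15.4-fold and Cdh1 2.06-fold lower, the latter by less than 2-fold when scaled to the median or with the refitted normexp correction; the list median lay inside the random range under 3 alternatives.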

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

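With 1 array per day, no alternative measures biological spread, and no paired analysis was possible because each day has 1 array. Scaling, the authors' table, the filters on dim probes and the choice of probe kept all 6 counts within 1.5 times, and removing saturated spots moved nothing, since there were none. Counts follow the threshold. At 1.5-fold, 5985 genes were lower on day 5 and 7113 lower on day 7 than on day 0, and 2311 were higher and 3502 lower on day 7 than on day 5. At 4-fold, 1509 were higher and 1232 lower on day 5, 1575 higher and 1519 lower on day 7, and 484 higher and 557 lower for day 7 against day 5. The planned normexp correction failed: its fitted background was -1249.9 on day 0, -13.4 on day 5 and -344.4 on day 7, against 5.7, 1.6 and 3.1 without spots of outlying local background. On day 0 and day 7 a few spots lay far under their local background (by down to -60712 and -9755.5), but on day 5 only down to -35. It gave 1724 higher and 9561 lower for day 5 against day 0 (15.3% higher, against 50.6%), 1577 and 8562 for day 7 against day 0 (15.6%, against 45.9%) and 6253 and 442 for day 7 against day 5 (93.4%, against 41.6%), with Foxa2 differences of 5.13, 4.65 and -0.48; its values for named genes and lists were not used. Refitted without outlying backgrounds, an alternative added after seeing this, it gave 2680 lower on day 7 than on day 0, 874 lower on day 7 than on day 5, and Foxa2 differences of 7.76 for day 5 and 7.54 for day 7 against day 0. Scaled to the median, the Foxa2 difference of day 7 against day 5 was -0.16. The number of lists standing apart was 20, 21 and 25, and from 17 to 26 under all alternatives. Of 526 named differences of at least 2-fold, 87 fell under 2-fold in at least 1 alternative, and 3 turned. Lss became -0.16 (day 5 against day 0) and Il17rd -0.013 (day 7 against day 0) with the median over probes, and Sox21 became 0.014 with that median and 0.033 with the refitted normexp (day 7 against day 0). The median of BMP targets for day 5 against day 0 became -0.18 over probes well above background on all arrays. Causes were not tested otherwise. Signal over background limits dim genes, where a fold is a bound.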

Other observations

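Gene lists outside the endoderm lineage also differed. Imprinted genes, expressed from 1 parental copy and abundant in growing embryos, were higher for 7 of 16 on day 5 (median log2 difference 0.85, random lists -0.60 to 0.33) and for 12 of 16 on day 7 (2.49, random -0.67 to 0.35) against day 0. On day 7, Peg3 was 17.9-fold, Igf2 17.7-fold and Dlk1 11.3-fold higher than on day 0, and Plagl1 was 16.4-fold higher than on day 5 (list median 1.16 for day 7 against day 5, random -0.24 to 0.13). DNA methylation and Tet enzymes had medians of -1.13 (random -0.75 to 0.72), -1.21 (random -0.81 to 0.73) and -0.33 (inside the random range) for day 5 against day 0, day 7 against day 0 and day 7 against day 5, the first of which was lost with the median over a gene's probes. Dnmt3l, the cofactor of de novo methylation, was 58.4-fold lower on day 5 and 328-fold lower on day 7, Tet1 5.97-fold and 7.50-fold lower, while the methyltransferase Dnmt3b was 4.02-fold and 2.15-fold higher. Glycolysis genes were lower on day 7 than on day 0 for 10 of 18 (median -1.03, random -0.67 to 0.08, and -0.64 in the authors' value table), against 4 of 18 on day 5 (median -0.46, inside the random range); day 7 against day 5 had a median of -0.29 (random -0.23 to 0.06), lost in the authors' value table. Cholesterol synthesis genes were higher for 5 of 16 on day 5 (0.46, random -0.58 to 0.28, and 0.73 in the authors' value table) and 6 of 16 on day 7 (0.87, random -0.68 to 0.30), and 0 of 16 differed 2-fold between day 5 and day 7 (0.34, random -0.22 to 0.12). The first of these was lost with the median over a gene's probes. Stress genes of p53 and the integrated stress response were lower for 8 of 17 on day 5 (-0.97, random -0.56 to 0.36) and 8 of 17 on day 7 (-0.92, random -0.68 to 0.35), Gadd45a by 8.87-fold and 5.83-fold. Cdkn1a was 2.63-fold higher on day 5, and Atf3 was 7.92-fold higher on day 7 than on day 5 (list median 0.12, at the edge of the random range of -0.26 to 0.12 and lost in 3 alternatives).

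Several lists of other lineages did not stand apart. Neuroectoderm genes (medians -0.18, -0.54 and -0.06 for day 5 against day 0, day 7 against day 0 and day 7 against day 5), lung and thyroid genes (0.00, 0.09 and 0.00) and pancreas genes (0.22, 0.00 and -0.45) lay inside the random range in all 3 comparisons in the main setting. The lung and thyroid list left that range over probes well above background on all arrays (1.47 for day 5 against day 0 and -1.77 for day 7 against day 5), with no filter on dim probes (0.30 for day 7 against day 5) and with the median over a gene's probes (0.90 for day 7 against day 0). Pax6 differed by -0.18, -0.86 and -0.68 (log2) in these comparisons at low signal, and by -2.38 and -2.08 in the last 2 with the median over its probes. Cpa1, a digestive enzyme of the pancreas, was nevertheless 27.6-fold higher on day 5 than on day 0. Blood and endothelium genes were inside the range against day 0 (-0.15 and -0.16) and above it for day 7 against day 5 (0.49, random -0.46 to 0.16). Kdr, a receptor of endothelial and mesodermal cells, was 38.1-fold higher on day 5 and 64.8-fold on day 7 than on day 0, and Gata1 was 23.1-fold lower on day 7 than on day 5. Trophoblast genes were inside the range against day 0 (-0.31 and -0.51, the latter -1.02 and below the range with no filter on dim probes) and below it for day 7 against day 5 (-1.38, random -0.46 to 0.20), Elf5 being 4.47-fold lower; this was lost with the refitted normexp correction and over probes well above background on all arrays. Intestine and stomach genes had a median of -0.05 on day 5 (inside the range) and 2.67 on day 7 (random -1.07 to 0.67, and 1.28 with no filter on dim probes) against day 0. Hox genes had -0.52 (inside, and -0.55, below the range, with the median over a gene's probes) and 0.77 (random -0.73 to 0.15, lost over probes well above background on all arrays). BMP targets had 0.59 on day 5 (random -0.61 to 0.51), lost in 2 alternatives. FGF targets had 0.58 (random -0.64 to 0.57), lost in 5 alternatives, and -0.10 on day 7 (inside), and Nodal and activin targets 0.57 on day 7 against day 0 (inside, and above with the refitted normexp correction). Germ cell and cleavage-stage genes had -2.52 on day 7 against day 0 (random -0.91 to 0.67) and -0.60 for day 7 against day 5 (random -0.52 to 0.22). Epiblast genes had 0.24 on day 7 against day 0 (inside). Reference genes had medians of -0.31, -0.48 and -0.10 (inside the range; the last above 0 when scaled to the median), and B2m was 5.76-fold higher and Tfrc 3.68-fold lower on day 7 than on day 0.

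For the 3 patterns weighed here, the tests were chosen only after the result was seen, except those on the second visceral endoderm list and the second mesoderm list, which were set before the values of those lists were seen. The first pattern is that secreted liver protein genes were higher on day 7 while Alb was at background on that array and extraembryonic endoderm genes were higher too. Scaling is argued against, since the liver protein median for day 7 against day 0 was at least 1.35 under the main and 5 other scalings. One candidate explanation is that part of the day 7 culture resembled visceral endoderm, the yolk sac layer that also makes Afp, Ttr and Apob. A second list of 16 visceral endoderm genes, with 0 on the lists fixed earlier, had a median of 1.30 for day 7 against day 5 (random -0.29 to 0.13), with 9 of 15 measured genes higher and 0 lower, Ctsh by 3.21 and Cited1 by 3.09 on the log2 scale. For day 5 against day 0 that list already had a median of 2.17, above the random range, with 10 of 15 higher and 1 lower. It thus also rose in the culture labelled definitive endoderm, and does not separate the 2 kinds of endoderm. Some of its genes, such as Soat2 and Selenop, are also expressed by liver (their number was not counted), and the labels name no sort, so early hepatic cells remain an open explanation, and with 1 culture and array per day a peculiarity of that culture cannot be told apart from the day.

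The second pattern is that mesenchyme, cardiac mesoderm and Hox genes were higher on day 7 than on day 5. Scaling is argued against, with a mesenchyme median of at least 1.51 under the main and 5 other scalings. A lower share of endoderm, raising all other cell types alike, was also weighed. The mesenchyme median lay 1.57 above that of the neuroectoderm genes, but many of those were near background, and a cell type that is absent cannot show it. General pluripotency (median -1.17, 0 of 12 higher) and epiblast genes (median -1.26, 0 of 10 higher), all measured on both arrays, were lower on day 7. Those lists did not rise, but cells leaving these states would lower them whatever the share of endoderm, so their fall cannot decide the question. Whether the endoderm cells also expressed those genes was not tested. A lower share of endoderm, raising all or only some other cell types, stays open. Mesodermal cells in the day 7 culture may contribute, but a second list of 24 mesoderm and mesenchyme genes, with 0 on the earlier lists, had a median of only 0.13 (random -0.34 to 0.11), with 6 of 23 measured genes higher, Pitx1 by 2.44 (log2), and 3 lower, Col6a2 at -1.36. Expression of collagens and Hox genes by the endoderm cells themselves was not tested, and with 1 culture and array per day a peculiarity of that culture cannot be told apart from the day.

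The third pattern is that LIF and STAT3 targets were higher on day 7 than on day 5, Klf4, Tfcp2l1 and Socs3 among them, without LIF in the medium. The median was at least 1.18 under the main and 5 other scalings, which argues against scaling. Regrowth of undifferentiated ES cells is argued against, because the 26 pluripotency genes outside that list had a median of -0.98, with 13 lower and 2 higher. Whether the BMP4 added after day 5 plays a part stays open, because the BMP target median of 0.72 says nothing of LIF and STAT3 targets. Basic FGF was added at the same time, and with 1 culture and array per day a peculiarity of that culture cannot be told apart from the day.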
